A study of Mus musculus with 4 samples.

How the data were processed

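Poly-A RNA of sorted CD4+ YFP+ Treg cells was sequenced in 4 libraries from mice carrying Foxp3 YFP-Cre, 2 with intact Pdpk1 (WT 1 and WT 2) and 2 with floxed Pdpk1 (KO 1 and KO 2). Per the labels, RNA was extracted with a column kit and libraries were made with a poly-A pull-down and an Illumina TruSeq kit. The deposited log2 values were made by the authors from counts, per the file headers and names. Per the submitters' processing notes, STAR, DESeq2 and the build mm10 were used, with no versions or order. The annotation, the counting tool, its use of strand, the handling of duplicate reads and the exact transform were not given in the sources used here. The deposited values ran from -2.1 to 13.94 with 2 decimals and had nearly no spread at the low end, as in a regularised log. Fold changes of low genes are then smaller than those of counts. No reads could be recovered from these values, so the depth of each library is unknown, no counting interval is given and no count model was run. Nothing says that libraries came from separate animals, so p-values of genes measure only the spread between these libraries.

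The table held 28334 rows and 4 value columns, each matched to 1 sample by its description. In 23 rows a date number stood in place of the gene symbol, and 19 symbols stood on more than 1 row. These rows were kept in the tests but not named or placed in lists. Genes were tested if 2 to the power of the deposited value was at least 10 in at least 2 libraries, which left 13685. Gene positions and transcript lengths came from GENCODE M21 (GRCm38, the assembly of mm10), matched by symbol in Python 3.11.15 for 97.3% of the tested genes (13322). Positions count from 1.

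KO was compared with WT by limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a moderated variance that follows the mean, genotype as the only term and 2 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over all tested genes, and a gene with an adjusted p under 0.05 is called higher or lower. SEs are those of this fit and SDs are over the 2 libraries of a group. Fold changes are 2 to the power of the difference of mean log2 values. The 34 gene lists, fixed before the data were examined, were tested with camera in limma with a preset correlation of 0.01, adjusted over the 34 lists. With the preset, camera sets a list against the spread over genes and takes genes as nearly independent. Its p-values therefore do not measure the spread between libraries alone. With an estimated correlation, camera has 2 degrees of freedom here and can hardly call a list, whatever the correlation. The counts of called members use the adjustment over all tested genes. A second count was adjusted over the list alone. Some genes stand on more than 1 list.

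The rule for named genes was also fixed before the data were examined. It took Pdpk1 and Foxp3, the 12 highest and 12 lowest log2 fold changes among called genes with non-overlapping groups and a mean linear value of at least 50 in the higher group, up to 4 called members of each list with the smallest p (up to 2 where none was called), and markers of other cell types and sex where needed. Predicted genes, unnamed clones, pseudogenes and segments of immunoglobulins and T cell receptors were passed over, 1 among the highest and 1 among the lowest. Some genes that met the rule are not reported here.

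The fit was tested on simulated log2 values of the 13685 genes with 200 changed. With independent libraries, 23% of 1.5-fold and 35% of 2-fold changes were recovered with 3 false calls. With simulated values adjusted for the replicate number, the same fit recovered 62% and 75% with 258 false calls, and 21.4% of unchanged genes had an unadjusted p under 0.05. With the replicate number as a term, the simulated fits made 0 false calls but recovered 0% at either size. In the data, 47.4% of the tested genes were called, a far larger share than the 200 of 13685 changed here. These simulated rates may therefore not hold for the data. In the simulated list test, the 1 shifted list was the only 1 called of 34. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are falsely called.

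Alternatives, whose effects are given in the closing section, were a term for the replicate number, no filter or a minimum of 100, a pseudocount of 10, quantile normalization, median centring, a variance prior without trend or with robust estimation, array weights, leaving out each library, a limit of 2-fold and, for lists, an estimated correlation, the fry test and a rank-based test. A correction of fold changes for transcript length and mean value (loess, span 0.4), the crossed pairing and a threshold of 0.1 with the replicate term were added after seeing the data.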

Results

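The messenger RNA of regulatory T cells (Treg), the CD4+ T cells that restrain other immune cells and depend on the transcription factor Foxp3, was measured by poly-A RNA-seq in C57BL/6 mice. The cells were sorted by flow cytometry as CD4+ and YFP+ from spleen and peripheral lymph nodes of untreated animals in which Foxp3 drives a fusion of YFP and the recombinase Cre. The titles of all 4 samples carry the tag hemizygous, and the genotype is written with a single copy of this X-linked Foxp3 allele. In 2 libraries, labelled WT, Pdpk1 was intact. In 2 libraries, labelled KO, Pdpk1 carried loxP sites for removal by Cre. Pdpk1 encodes PDK1, the kinase that phosphorylates AKT and other AGC kinases. The deposited table held normalised log2 values of 28334 rows in 4 libraries, and 13685 genes entered the tests. Reads per library were not given. The median log2 value of the tested genes was 8.77 in each WT and 8.80 in each KO library, and the 100 most abundant genes held 6.38% to 6.66% of the summed linear values. The series title holds that Treg cells need PDK1 to keep their function.

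Pdpk1 itself did not differ between the groups. The gene lies on the minus strand of chromosome 17 (mm10, 24073680 to 24150924). Its log2 value was 11.74 ± 0.04 (SD, n = 2) in the libraries labelled WT and 11.76 ± 0.04 (SD, n = 2) in the libraries labelled KO, a log2 fold change of 0.02 with a 95% interval of -0.06 to 0.10 (adjusted p = 0.612). The labels do not state which exons the loxP sites flank, and a value summed over a gene keeps the reads of the exons that remain, so this value neither shows nor excludes the deletion and the groups are named by their labels throughout. Foxp3 (chromosome X, 7573644 to 7595245, plus strand) was at 11.40 ± 0.03 and 11.45 ± 0.04 (SD, n = 2 each), a log2 fold change of 0.05 (adjusted p = 0.247). The libraries separated by genotype over all tested genes. The first principal component, with WT on one side and KO on the other, held 85.1% of the variance. The second, with 14.2%, set WT 1 and KO 2 against WT 2 and KO 1.

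Between the genotypes, 3703 genes were called higher and 2778 lower in the libraries labelled KO, 6481 of the 13685 tested. The excess of higher genes depended on the scaling, with 3029 higher and 3067 lower after quantile normalization and 2983 and 3250 after median centring. It was also absent after a joint correction for transcript length and mean value (2557 higher and 2754 lower). Most of these differences were small. The median absolute log2 fold change of a called gene was 0.24, and 266 called genes changed at least 2-fold, 159 of them higher and 107 lower. The 12 genes with the highest log2 fold changes reached from 2.16 to 2.88. They were led by Nos1 (chromosome 5, 117781032 to 117958840), the neuronal nitric oxide synthase, which was 7.34-fold higher (log2 fold change 2.88, SE 0.08). Gzma (chromosome 13, 113093825 to 113100981), a serine protease of cytotoxic granules, was 5.50-fold higher (2.46, SE 0.07), at 5.58 ± 0.10 in WT and 8.04 ± 0.03 in KO (SD, n = 2 each). Hapln1, a link protein of hyaluronan matrix, was 6.13-fold higher (2.62, SE 0.05), and the matricellular protein gene Smoc2 was 7.09-fold higher with a wider spread (2.83, SE 0.32). Others were the Wnt regulator Dact2 (2.67), the glycosphingolipid enzyme B4galt6 (2.71), the mucins Muc13 (2.59) and Muc4 (2.30), Dlk1 (2.32), the protease Bace2 (2.23) and the unconventional myosin Myo16 (2.16). Those named were low in WT, between 3.29 (B4galt6) and 5.58 (Gzma) on the log2 scale.

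The 12 genes with the lowest log2 fold changes reached from -1.79 to -1.36. Gpr15 (chromosome 16, 58717433 to 58719070), a receptor that guides T cells to the large intestine, was 3.45-fold lower in KO (-1.79, SE 0.04), at 8.65 ± 0.01 in WT and 6.87 ± 0.05 in KO (SD, n = 2 each). Cd38, an NAD-consuming surface enzyme, was 2.88-fold lower (-1.53, SE 0.12). Tnfsf14, which encodes the cytokine LIGHT, was 2.56-fold lower (-1.36, SE 0.05), and the receptor gene Cd160 was 2.66-fold lower (-1.41, SE 0.15). Others were the axonemal dynein Dnah7a (-1.70), the smooth muscle actin Actg2 (-1.67), the meiotic cohesin Rec8 (-1.64), the metalloprotease Adam12 (-1.58), Cecr6 (-1.57), the carboxylesterase Ces2c (-1.47) and the matrix protein Matn2 (-1.43). Dnah7a, Actg2 and Ces2c have close paralogs that can share reads. Adjusted p was 0.00434 to 0.00968 for the 24 genes, which were chosen among called genes with non-overlapping groups.

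**Figure D1:**
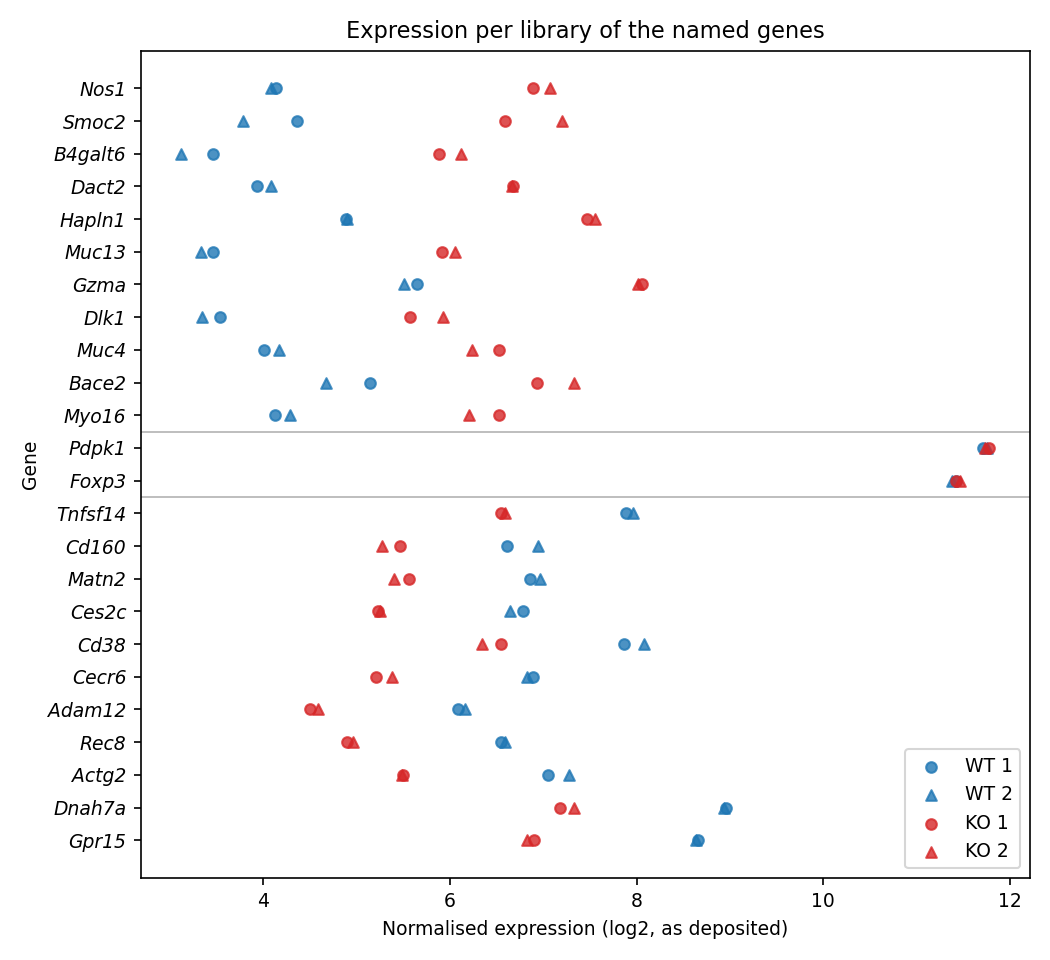
Normalised expression (x axis, log2 as deposited) of the named genes among the 12 highest and the 12 lowest log2 fold changes and, between the grey lines, of Pdpk1 and Foxp3, with a point for each library (WT blue, KO red, circles replicate 1, triangles replicate 2). Pdpk1 and Foxp3 overlapped between the groups, whereas Nos1 was at 4.08 and 4.13 in WT and at 6.89 and 7.07 in KO, and Gpr15 at 8.64 and 8.66 in WT and at 6.83 and 6.90 in KO.

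The precision of these calls was limited by the deposited values, in which libraries of the same number cancelled to less than the counting error that the linear values would have as reads (given with the closing observations). If the values were adjusted for the replicate number before deposit, SDs, SEs and p-values from a fit without that term are too small. The share of variance of the first principal component and the correlations within groups would then be too large. With the replicate number as a term in limma, 0 genes were called at adjusted p under 0.05 (smallest adjusted p 0.0964, 4881 genes at unadjusted p under 0.05), and 2203 genes, all among the 6481, had an adjusted p under 0.1, the 24 above included.

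The cell cycle list held the largest share of called members. Of 42 measured members, 41 were called higher in KO and 0 lower, with a median log2 fold change of 0.64 (camera adjusted p = 4.8e-11 with a preset and adjusted p = 0.819 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitosis, was 1.74-fold higher (0.80, SE 0.02), the mitotic kinase gene Aurka 1.72-fold (0.79, SE 0.04), cyclin A2 (Ccna2) 1.60-fold (0.68, SE 0.04) and the replication factor Gins2 1.60-fold (0.68, SE 0.03). Adjusted over the list alone, 41 were higher as well. Among 18 measured replication-dependent histone genes, 6 were called higher and 1 lower, and the list was not called (adjusted p = 0.478, median 0.17). Of 59 listed histone genes only these 18 were measured in the poly-A libraries, at a low median log2 value of 4.42. The list therefore neither adds to the cell cycle result nor speaks against it.

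Changes among genes of energy metabolism were small. In the oxidative phosphorylation list, 36 of 43 members were called higher and 0 lower (38 and 0 adjusted over the list alone), with a median of 0.15 (adjusted p = 1.9e-08, but adjusted p = 0.80 with an estimated correlation). Sdhd, a subunit of succinate dehydrogenase, was 1.19-fold higher (0.26, SE 0.02), and Uqcrfs1, the Rieske protein of complex III, 1.18-fold (0.24, SE 0.02). Of 26 glycolysis genes, 14 were called higher and 5 lower (15 and 5 adjusted over the list alone), and the median was 0.11. In camera, the list passed the threshold only with the replicate term (adjusted p = 0.0559 without and 0.0489 with it). With an estimated correlation it did not pass (adjusted p = 0.819). Its median was 0.11 without WT 1, 0.1475 without WT 2, 0.1175 without KO 1 and 0.155 without KO 2. Pgk1, phosphoglycerate kinase, was 1.21-fold higher, and lactate dehydrogenase A (Ldha) 1.14-fold. In the list of amino acid supply and targets of the stress factor ATF4, 16 of 24 were called higher and 4 lower (17 and 4 adjusted over the list alone; adjusted p = 0.0117, but adjusted p = 0.819 with an estimated correlation; median 0.13). Its members included the pseudokinase gene Trib3 at 1.79-fold (0.84, SE 0.04) and asparagine synthetase (Asns) at 1.55-fold (0.64, SE 0.04). Of 88 ribosomal protein genes, 33 were called higher and 1, Rpl24, lower (28 and 1 adjusted over the list alone), with a median of 0.07 (adjusted p = 2.2e-05, but adjusted p = 0.819 with an estimated correlation). That median turned to -0.04 after the correction for transcript length and mean value given below.

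Transcripts of Treg identity and effector function went both ways. Of 27 Treg identity genes, 12 were called higher and 5 lower, the same counts as adjusted over the list alone, and the list was not called (adjusted p = 0.123, median 0.09). The IL-2 receptor chain Il2ra was 1.17-fold higher (0.23, SE 0.01), Lrrc32, which encodes the TGF-β docking protein GARP, 1.24-fold (0.31, SE 0.01) and the cytokine signalling inhibitor Socs2 1.75-fold (0.81, SE 0.05). Itgb8, an integrin chain that activates TGF-β, was 1.72-fold lower (-0.78, SE 0.02). In the effector Treg list, 16 of 30 were called higher and 6 lower (17 and 6 adjusted over the list alone). Its camera adjusted p was 0.0559, and 0.0440 with the replicate term, but 0.819 with an estimated correlation. The median was 0.24, and 0.23 without WT 1, 0.24 without WT 2, 0.2075 without KO 1 and 0.29 without KO 2. The inhibitory receptor gene Lag3 was 2.41-fold higher (1.27, SE 0.03), the transcription factor genes Prdm1 (Blimp-1) and Irf4 were 1.89-fold and 1.40-fold higher, and the inhibitory receptor gene Pdcd1 was 1.42-fold lower (-0.51, SE 0.01). Of 17 genes for suppressive molecules, 9 were called higher and 2 lower, also adjusted over the list alone (adjusted p = 0.0559, and 0.0489 with the replicate term, but adjusted p = 0.819 with an estimated correlation; median 0.16). Of 20 genes of resting cells and lymphoid homing, 6 were called higher and 4 lower (6 and 5 adjusted over the list alone; adjusted p = 0.873). The IL-7 receptor gene Il7r was 1.44-fold higher and the transcription regulator Id3 1.23-fold lower. The median of that list was 0.04 and its mean -0.02.

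Among the lists of helper T cell programmes, Th17 was called without the replicate term, and Th17 and Tfh with it, but neither with an estimated correlation. Of 8 measured Th17 genes, 5 were called lower and 1 higher, also adjusted over the list alone (adjusted p = 0.0392, but adjusted p = 0.819 with an estimated correlation, median -0.44). The chemokine receptor gene Ccr6 was 2.14-fold lower (-1.10, SE 0.03) and the ligand-activated transcription factor gene Ahr 1.55-fold lower (-0.63, SE 0.01), while the leukotriene receptor gene Ltb4r1 was 1.89-fold higher. Of 12 follicular helper (Tfh) genes, 8 were called lower and 3 higher, the same adjusted over the list alone (adjusted p = 0.0559, and 0.0489 with the replicate term, but adjusted p = 0.819 with an estimated correlation; median -0.43). The lineage factor gene Bcl6 was 2.05-fold lower (-1.04, SE 0.03), the follicle-homing receptor gene Cxcr5 2.31-fold lower (-1.21, SE 0.05), and Slamf6 1.34-fold higher. Of 12 Th2 genes, 7 were called higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.0625, median 0.31). The cytokine gene Il4 was 3.18-fold higher (1.67, SE 0.09), Pparg 2.32-fold (1.22, SE 0.07) and Nfil3 1.68-fold (0.75, SE 0.02). Of 19 Th1 genes, 7 were called higher and 5 lower (8 and 7 adjusted over the list alone; adjusted p = 0.810, median 0.06, and 0.01 without WT 1, 0.10 without WT 2, 0.03 without KO 1 and 0.09 without KO 2). The IL-12 receptor chain Il12rb2 was 3.42-fold higher (1.78, SE 0.05), the chemokine gene Ccl5 1.70-fold higher and Tnf 1.31-fold lower.

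Of 32 genes of the type I interferon response, 13 were called lower and 1 higher (16 and 2 adjusted over the list alone), with a median of -0.21 (adjusted p = 0.000667, but adjusted p = 0.886 with an estimated correlation). The antiviral genes Oasl1, Rsad2 and Mx1 were 1.83-fold, 1.51-fold and 1.47-fold lower. Of 26 genes of the interferon gamma response, 13 were called higher and 0 lower (13 and 1 adjusted over the list alone; adjusted p = 0.00745, but adjusted p = 0.937 with an estimated correlation; median 0.11). The 4 with the smallest p were guanylate-binding proteins, with Gbp2 1.60-fold and Gbp3 1.48-fold higher. These belong to a family of similar sequences that can share reads. In the list of the IL-2 receptor and STAT5 signalling, 9 of 16 were called higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.0144, but adjusted p = 0.819 with an estimated correlation, median 0.12). The kinase gene Pim1, induced by STAT5, was 1.29-fold higher (0.37, SE 0.01).

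Components of the pathway around PDK1 showed no common direction. Of 34 genes for PI3K, AKT, mTOR and AGC kinase components, 9 were called higher and 7 lower (10 and 9 adjusted over the list alone; adjusted p = 0.810), with a median of 0 and a mean of -0.005. Akt1 was 1.14-fold and the PI3K regulatory subunit Pik3r5 1.28-fold higher, and the mTORC1 subunit Rptor 1.17-fold lower.

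**Figure D2:**
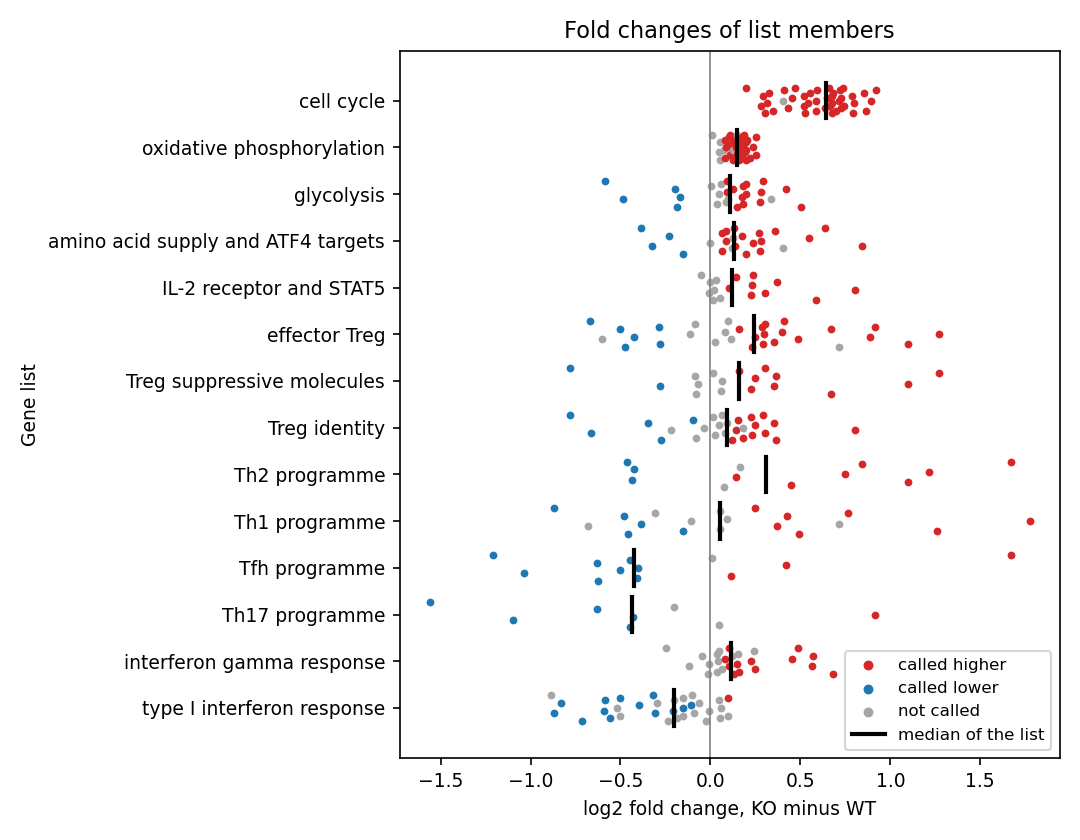
Log2 fold change (x axis, KO minus WT) of every measured member of 14 gene lists, coloured by its call in limma at adjusted p under 0.05, with the median of each list as a black bar. Cell cycle genes lay to the right of 0 with a median of 0.64, and the medians of the Th17 and Tfh lists were -0.44 and -0.43.

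In the camera test, 8 of 34 lists were called, 6 higher (cell cycle, oxidative phosphorylation, ribosomal proteins, interferon gamma response, amino acid supply and ATF4 targets, IL-2 receptor and STAT5) and 2 lower (type I interferon response, Th17). This test used a preset correlation between genes. With an estimated correlation, 0 lists were called (smallest adjusted p 0.80). Both that test and its estimates rest on 2 residual degrees of freedom. Calls were lost even where the estimate lay below the preset 0.01, at 0.007 for oxidative phosphorylation and -0.10 for Th17. So this loss does not show that correlation between genes made the calls. The estimates were 0.98 for cell cycle, 0.70 for type I interferon and 0.74 for interferon gamma. With the preset, p-values of these lists may be far too small. With the replicate term and adjusted over each list alone, the called members were 40 of cell cycle and 22 of oxidative phosphorylation. They were 6 each of amino acid supply, interferon gamma and IL-2 receptor and STAT5, 5 of Th17, and 0 of ribosomal proteins and type I interferon. Lists that camera did not call ranged as widely, with 19 of effector Treg, 16 of chemokine receptors and adhesion, 14 of Treg identity and 0 of NF-kB targets. These counts therefore do not set the called lists apart. They were not adjusted across lists, and adjusted over all tested genes the same fit called 0. Short transcripts had slightly higher fold changes than long ones, with medians of 0.05 and -0.03 in the 3331 shortest and the 3330 longest. After a joint correction for transcript length and mean value in the annotated genes alone, chosen after the data were seen, the ribosomal protein list turned to a median of -0.04 (adjusted p = 0.0474), and 3 other lists were not called. The median went from 0.11 to 0.03 for interferon gamma (SD over members 0.22 before and 0.21 after, adjusted p = 0.292) and from 0.12 to 0.05 for IL-2 receptor and STAT5 (SD 0.24 and 0.23, adjusted p = 0.148). The oxidative phosphorylation list stayed called, but its median went from 0.15 to 0.05 (SD 0.05 and 0.06, adjusted p = 0.00238). For Th17 the median went from -0.44 to -0.37 (SD 0.74 and 0.73, adjusted p = 0.119). The Th17 call was also lost where its median stayed similar or grew, at -0.42 without WT 1 (adjusted p = 0.0539), -0.46 without KO 1 (0.0664), -0.53 with the stricter filter (0.0812), -0.42 with quantile normalization (0.0701), -0.47 with median centring (0.0501) and -0.44 with the rank test (0.0580). The IL-2 receptor and STAT5 call was lost at a median of 0.11 without WT 2 (adjusted p = 0.0510), 0.12 with the stricter filter (0.0549) and 0.08 with quantile normalization (0.0662). By the fry test, which does not set a list against the other genes, type I interferon (adjusted p = 0.179), interferon gamma (0.0897) and ribosomal proteins (0.0760) were not called.

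Transcripts of other cell types were present at varied levels, and none of their lists was called. Of 19 B cell genes, 3 were called lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.478, median -0.28). That median was -0.02 without WT 1, -0.54 without WT 2, -0.17 without KO 1 and -0.38 without KO 2. Cd22 was 2.20-fold and Cd79a 1.54-fold lower and Ighm 1.27-fold higher in KO. Ighm stood at 11.10 in WT. Of 15 myeloid and neutrophil genes, 2 were called lower and 1 higher (1 and 0 adjusted over the list alone; adjusted p = 0.523). Of 6 dendritic cell genes, 1 was called lower and 2 higher, as adjusted over the list alone (adjusted p = 0.951), with Xcr1 1.85-fold lower. Of 9 CD8 T and NK cell genes, 2 were called higher and 1 lower, as adjusted over the list alone (adjusted p = 0.860). One of these was Gzma, while Klrb1c was 2.07-fold lower, Cd8a was at 4.57 to 4.87 and Cd8b1 at 7.93 to 8.01. Of 9 plasma cell genes, 1 was called higher (Derl3) and 1 lower (Sdc1), as adjusted over the list alone (adjusted p = 0.694). Of 4 stromal and endothelial genes, 2 were called lower and 1 higher, as adjusted over the list alone (adjusted p = 0.665), with Col1a2 2.91-fold lower. Of 7 erythroid and platelet genes, 1 was called lower (0 adjusted over the list alone; adjusted p = 0.873). Of 10 genes of conventional CD4 T cells, 3 were called higher and 2 lower, as adjusted over the list alone (adjusted p = 0.873), with Cd40lg 1.57-fold lower.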

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

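The crossed pairing, the length correction (for length and mean value jointly, annotated genes only) and the 0.1 threshold were chosen after seeing the data. The 6481 calls became 7782 with no filter, 5003 with the stricter filter (1788 lower), 6456 with a pseudocount, 6096 with quantile normalization (3029 higher and 3067 lower), 6233 with median centring (2983 higher and 3250 lower), 5909 with no trend, 6337 with a robust prior, 6462 with array weights and 5311 with length correction (2557 higher and 2754 lower). A limit of 2-fold left 266 (159 higher, 107 lower). With the replicate block, limma called 0 genes, 0 higher and 0 lower (4881 at unadjusted p under 0.05), also with length correction (0, 0 and 0, and 4017). With the block at 0.1, 2203 were called (1363 higher, 840 lower). Leaving out any 1 library gave 0 to 0 calls (5225 to 5669 at unadjusted p under 0.05), with 1 residual degree of freedom and the lone library assumed to vary like the other group. The replicate numbers are not said to mark a shared litter or day, and the crossed pairing called 9728 genes (4446 lower). Voom was not run, as no reads could be recovered. The cause of these changes was not tested, apart from the fewer libraries or genes.

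The first principal component held 80.1% to 87.7% under the scalings and filters. The Pdpk1 log2 fold change was -0.0275 with quantile normalization, -0.01 with median centring and -0.005 to 0.045 without 1 library. Of 34 lists, 12 were called with the block or no filter, 11 with median centring or fry, 8 with ranks, 7 to 10 without 1 library, 5 with length correction and 0 with an estimated correlation. With the block, effector Treg (adjusted p = 0.0440) and suppressive molecules, Tfh and glycolysis (0.0489 each) were added and no call was lost. Lists not called at first passed with no filter (effector Treg, suppressive molecules, Tfh, glycolysis), quantile normalization (Th2), median centring (effector Treg, suppressive molecules, Th2, glycolysis), ranks (suppressive molecules), fry (Treg identity, suppressive molecules, Th1, Th2, Tfh, heat shock), length correction with the block (effector Treg, Th2, Tfh, heat shock), without WT 1 (mitochondrially encoded genes, adjusted p = 0.0284) and without WT 2 or KO 2 (effector Treg and glycolysis, 0.0422 and 0.0339). Medians of lists changed sign for B cells (0.365, stricter filter), dendritic cells (0.00014, pseudocount) and, with quantile normalization, resting Treg (-0.0084), apoptosis (-0.0019) and CD8 T and NK cells (0.0056). With length correction, with or without the block, they did for Treg identity (-0.0027), resting Treg (-0.019), NF-kB (-0.039), sterol synthesis (0.00094), apoptosis (-0.019), ribosomal proteins (-0.037) and mitochondrially encoded genes (-0.044), and fold changes did for Foxp3 (-0.021), mt-Nd6 (-0.030), mt-Nd5 (-0.048) and mt-Nd4 (-0.040). Without 1 library, medians ran from -0.065 to 0.065 for sterol synthesis, -0.11 to 0.04 for CD8 T and NK cells, -0.275 to 0.16 for myeloid cells, -0.125 to 0.0025 for dendritic cells, -0.0175 to 0.06 for resting Treg, -0.065 to 0.1625 for conventional CD4 T cells and -0.0525 to 0.005 for heat shock. Those of other lists that moved over 1.5 times ran from 0.085 to 0.11 for chemokine receptors, -0.535 to -0.015 for B cells, 0.32 to 2.31 for sex-linked genes, 0.01 to 0.1 for Th1, 0.135 to 0.705 for plasma cells and -0.115 to 0.115 for erythroid cells. The cause of the reversals was not tested. Depth is unknown, so its limit could not be stated.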

Other observations

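All tests of explanations in this part were chosen after the results were seen. Among 29 chemokine receptor and adhesion genes, 12 were called higher and 7 lower (13 and 7 adjusted over the list alone; camera adjusted p = 0.478), with a median of 0.16 and a mean of -0.03. That median was 0.11 without WT 1, 0.10 without WT 2, 0.09 without KO 1 and 0.11 without KO 2. Lower Gpr15, Ccr6 and Cxcr5 stood beside a 1.37-fold higher Ccr4, a receptor for skin homing. Of 28 genes of T cell receptor signalling and the immediate early response, 11 were called higher and 5 lower (12 and 6 adjusted over the list alone; adjusted p = 0.446), with Dusp5 1.29-fold and Myc 1.22-fold higher. Of 25 NF-kB targets, 9 were called higher and 4 lower (9 and 5 adjusted over the list alone; adjusted p = 0.666), with Bcl3 1.19-fold higher. Of 22 apoptosis regulators, 6 were called higher and 2 lower, as adjusted over the list alone (adjusted p = 0.226). Pmaip1 (Noxa) was 1.48-fold and Cdkn1a (p21) 1.41-fold higher, and the BH3-only gene Bmf was 1.61-fold lower.

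Of 14 heat shock genes, 3 were called higher and 4 lower, as adjusted over the list alone (adjusted p = 0.523). The inducible Hsp70 genes Hspa1b and Hspa1a were 2.40-fold and 2.39-fold lower in KO. They are near-identical copies that share reads, and such genes are also induced by handling of cells. The mitochondrial chaperone gene Hspd1 was 1.14-fold higher. Of 31 sterol and fatty acid synthesis genes, 7 were called higher and 2 lower, as adjusted over the list alone (adjusted p = 0.810), with a median of -0.02 and a test direction of higher. Elovl6 was 1.25-fold and Acly 1.10-fold higher and Acss2 1.16-fold lower. Of 10 mitochondrially encoded genes, 3 were called higher and 0 lower (0 adjusted over the list alone, camera adjusted p = 0.123, and 0.952 with an estimated correlation). Their median was 0.08, and 0.10 without WT 1, but it turned to -0.04 after length correction (camera adjusted p = 0.336). In the CD8 T and NK list the median was -0.01 and the mean 0.12, and the erythroid list had a median of 0 and a mean of -0.03.

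Libraries of the same number deviated from their group means in opposite directions (correlation across genes -0.907, genes not being independent replicates). The contrast of replicate 1 with replicate 2, summed over both genotypes, had a spread of 0.20 to 0.40 times that of the crossed contrast in the 10 abundance bins. Both an adjustment of the values for the replicate number before deposit and handling of WT 1 with KO 2 and of WT 2 with KO 1 could give such ratios, which follow from that correlation. With linear values taken as reads, the contrast was 0.198 to 0.534 times the counting error in genes above 8 on the log2 scale. Independent sampling noise cannot fall below counting error. On that reading, the ratios to counting error argue against shared handling as the only cause. Depth and transform are unknown, so this holds only if the linear values are near the read counts. What the contrast kept was largest for Xist (0.69). The median size of the contrast was 0.29 in the B cell list and 0.22 in the myeloid list, above all 10000 random lists of matched abundance. The random medians were 0.04 and 0.05. The Treg identity list, at 0.02 with a random median of 0.02, still lay above 95.3% of its random lists. Members of a marker list may vary together, unlike random genes, so these ranks can overstate an excess. The numbered pairs may have differed in sex and cell content. The mean of the Y-linked genes varied more along the crossed contrast. It was lower in WT 1 and KO 2 (5.65 and 7.28) than in WT 2 and KO 1 (7.61 and 8.81). No biological explanation was tested.

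Pdpk1 was not lower in the libraries labelled KO. A candidate explanation is a deleted part too short to lower the value summed over the gene. The 95% interval with the replicate term allows a loss of at most 7.90% of the signal, but the deleted part is not stated, so this cannot be decided here. An exchange of the labels of a WT and a KO library of the same number is argued against by the correlations. These were at least 0.998 within a group and at most 0.991 between groups. An exchange between different numbers would make the true genotype contrast that of replicate 1 with replicate 2. An adjustment for the replicate number would have removed that contrast, so the correlations cannot decide on such an exchange. Whether cells that kept intact Pdpk1 were present was not tested.

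Xist, which is transcribed from the inactive X chromosome of female cells, and Y-linked genes were both present in the 4 libraries, although the genotype is written with a single copy of the X-linked Foxp3 allele. Xist was at 11.34, 10.56, 10.43 and 10.52 and the mean of Ddx3y, Eif2s3y, Kdm5d and Uty at 5.65, 7.61, 8.81 and 7.28 in WT 1, WT 2, KO 1 and KO 2. The sex-linked list was not called (adjusted p = 0.810, median 1.29, 0 of 5 members called, also adjusted over the list alone), and its median was 0.32 without WT 1, 2.31 without WT 2, 0.55 without KO 1 and 2.09 without KO 2. Cells of 1 sex each, and of opposite sexes, in WT 1 and KO 1 are argued against by Xist, which differed by only 0.91 between them. A mixture of cells of both sexes is a candidate explanation, since the 4 Y-linked genes kept their ratios within 0.225 over libraries while their mean ranged by 3.17, but it cannot be decided from values that may have been adjusted.

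The linear value per base of transcript was 1.42-fold apart between the first and the 20th gene in rank, with transcripts of 499 to 3593 bases among these.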
